A study of Mus musculus with 12 samples.

How the data were processed

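Bulk RNA sequencing of mouse ear skin was analysed in 12 libraries. They fall into 4 groups of 3 by housing and treatment. Mice were kept under specific-pathogen-free (SPF) or germ-free (GF) conditions, and the skin received ethanol, the vehicle, or MC903 in ethanol. MC903 is calcipotriol, a vitamin D analogue that produces inflammation resembling atopic dermatitis when put on mouse skin. The labels give 5 applications, in a wording that leaves open whether this was 1 per day or more. SPF libraries carry the labels 1, 2 and 3 and GF libraries 1, 4 and 5, each label once with ethanol and once with MC903. The labels do not say whether libraries with the same label came from the same mouse, or that the replicates came from separate mice, so p-values measure the spread between these libraries. The strain is given as C57BL/6 in 9 libraries. The label ends in 7 for GF MC903 4, in 8 for GF ethanol 5 and in 9 for GF MC903 5, a count that runs with the order of the samples.

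RNA was prepared with a fibrous tissue kit, and libraries with a TruSeq RNA kit sequenced on a HiSeq4000, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0 and StringTie 1.3.4d with the mm10 build. The order and settings of these tools, the annotation and the use of strand are not given in the sources used here, so reads of overlapping genes and of near-identical copies could not be separated. Per the file headers, the authors deposited 1 table with an estimated count and an FPKM value per gene and library, under Entrez gene identifiers. The deposited estimated counts are whole numbers. In 162 values up to 50 of single-transcript genes, 100% equalled the count implied by the deposited FPKM value rounded up, within a tolerance of 0.01, and whether the counts equal tallies of reads was not tested. The main result of every test uses these counts as deposited. The FPKM values served only for that check and for the length of each gene implied by both columns.

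Totals lay between 36358294 and 48225425 estimated counts per library. Of 24532 genes in the table, 4221 were at 0 in every library. 16466 passed edgeR's filterByExpr by group (minimum count 10, minimum total 15) and were tested, and 8066 were not. Identifiers matched a RefSeq table of GRCm38.p6 for 24462 genes. Coordinates are from that table, which uses the same build as mm10. Every pair of replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom between 17.9 and 47.2 in 12 pairs, so each library counted as 1 replicate. Expression is given as CPM, counts scaled by edgeR's cpm function on TMM-scaled library sizes, as mean ± SD over 3 libraries.

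Each comparison was tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) in 1 fit of all 12 libraries with a coefficient per group, TMM scaling, and Benjamini-Hochberg adjustment over the genes tested at 0.05. The common dispersion was 0.022. The comparisons were the response to MC903 in SPF skin, the response in GF skin, the difference between these responses (GF minus SPF), and GF minus SPF skin with ethanol and with MC903. Every adjusted p given for a gene is from this test. The comparisons of responses share no libraries with each other, nor do the comparisons of housing. Mean TMM factors were 1.23 and 1.19 in SPF and GF ethanol libraries and 0.83 in both MC903 groups. Fold changes are therefore relative to a scaling that moves the median gene. On library totals alone the median log2 fold change shifted by -0.58 for the SPF response, -0.51 for the GF response, 0.06 for their difference, -0.05 between ethanol groups and 0.01 between MC903 groups.

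A set of 30 gene lists was fixed before the data were examined. They hold type 2 cytokines and alarmins, vitamin D targets, chemokines for eosinophils and T cells, markers of neutrophils, basophils and mast cells, eosinophils, T cells, dendritic and Langerhans cells, macrophages and monocytes, and B and plasma cells, genes of the cornified envelope, of stressed keratinocytes, of proliferation, of epidermal ceramides, of sebaceous lipid synthesis, of adipocytes, skeletal muscle, cartilage, hair follicle, fibroblasts and matrix, antimicrobial defence, interferon response, the IL-17, IL-22 and IL-1 axis, Schwann cells, endothelium, melanocytes, red blood cells, aryl hydrocarbon receptor targets, the circadian clock, and immediate early and heat shock genes. Lists were tested against other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Each list was also tested by camera with a correlation estimated per list. Then 0 of 28 lists passed in each comparison, and the lists with an unadjusted p under 0.05 numbered 5 for the SPF response, 5 for the GF response, 2 for their difference, 5 between ethanol groups and 3 between MC903 groups. The lists of eosinophils and of red blood cells had fewer than 5 tested members and got no set test. Counts of members that passed are given over all genes tested and adjusted over the list alone. The SE of a list median comes from the spread over its genes, counted as independent. It leaves out the spread between libraries and the correlation within a list, so it can be too small. That correlation was estimated at 0.25 for muscle, 0.14 for interferon and 0.36 for dendritic cell genes. Flg and the constant genes of the T cell receptor and of immunoglobulins were on the lists and are not analysed here.

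The genes named in the text follow a rule fixed before the data were examined. It takes, per comparison, up to 8 genes that rose and 8 that fell most among those past the threshold with a mean log2 CPM of at least 1 and no overlap between groups (no overlap rule for the difference of responses), up to 4 members of each list with the smallest p, and 19 genes whatever their values. Names that start with Gm and a digit or with LOC, or end in Rik, were left out. Only part of the genes given by the list part of the rule are named, and that part was chosen with the values in view. Genes outside the rule are said to be so where they appear. Where every library of a group was at 0, a fold is a lower bound against a floor of 3 counts over the group, for counting error only.

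Alternatives fixed beforehand were DESeq2 size factors, library totals without scaling factors, no filter and a filter of at least 50 counts in 3 libraries, the DESeq2 1.42.0 Wald test, limma voom, fits of only the libraries compared, a replicate block, each library left out in turn, the mean of the skeletal muscle list as a covariate, and a 2-fold minimum. Removal of a per-library trend with gene length, and the exclusion of genes whose estimate switched between libraries of a group, were added after the data were seen. A gene counted as switching where its highest library in a group had at least 10 CPM and its lowest was lower by at least 16-fold. The closing test of such genes was also run at 4-fold and 8-fold, and its first threshold, 4-fold, was set with the values per library in view. The thresholds of most closing tests and 5 further gene groups were also chosen after the data were seen. The tests were checked on simulated counts for the real genes and depths with 200 changed genes. The share of 2-fold changes found was 86% for the SPF response, 85% for the GF response, 59% for their difference, 91% between ethanol groups and 88% between MC903 groups. For 4-fold changes it was 98%, 99%, 93%, 98% and 99% in the same order. False calls made up 5.6%, 2.6%, 3.2%, 2.1% and 7% of the calls in that order. These simulated genes were independent, with as many rises as falls, no length trend and otherwise the same mean in every group. In the data far more genes changed, 12149 of 16466 in the SPF response, so these shares may not hold there. In simulated ethanol groups with a length trend and no other change, 449 genes were called before and 0 after removal of the trend. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.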

Results

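Gene expression was measured by bulk RNA sequencing in ear skin of SPF and GF mice after ethanol or MC903. Each of the 4 groups held 3 libraries. The series asks how the microbiota bears on skin inflammation that resembles atopic dermatitis, so the comparisons follow the response to MC903 in each housing, the difference between these responses, and the difference between housings under each treatment. Totals lay between 40196604 and 43952521 estimated counts in SPF ethanol libraries and between 36358294 and 48225425 in SPF MC903 libraries. They lay between 40015323 and 41271713 in GF ethanol libraries and between 41813901 and 43404010 in GF MC903 libraries. The 10 highest genes took 7.2 to 8% of the counts of each ethanol library, 8.5 to 9.5% with MC903 in SPF skin and 10.8 to 11.5% with MC903 in GF skin. The first principal component held 69% of the variance and separated the treatments. The second held 11.6% and separated the housings, with SPF libraries between -50 and -16.1 and GF libraries between 9.6 and 43.9. Floors for genes at 0 cover counting error only.

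In SPF skin, MC903 raised the alarmin Tslp, the vitamin D target Cyp24a1 and the wound keratins Krt6a and Krt16 by log2 changes between 7.14 and 10.12. Tslp (gene ID 53603, GRCm38 chromosome 18, 32815383 to 32819799), a keratinocyte cytokine that promotes type 2 immunity, rose from 2.46 ± 0.198 to 2627 ± 139 CPM (SD, n = 3), a log2 change of 10.06 (SE 0.26, adjusted p = 5.1e-11). Cyp24a1 (ID 13081, chromosome 2, 170482957 to 170497145), the enzyme that breaks down active vitamin D, rose from 65.7 ± 32.7 to 9290 ± 1390 CPM (log2 change 7.14, adjusted p = 1.1e-08). Krt6a (ID 16687, chromosome 15, 101689928 to 101694305), a keratin of wounded epidermis, rose from 80.4 ± 9.4 to 12060 ± 1490 CPM (log2 change 7.23, adjusted p = 7.6e-11). Krt16, its partner keratin, rose by 10.12 on the log2 scale. Of 16466 genes tested, 12149 changed, 5755 up and 6394 down, and 5679 of them by at least 2-fold. On library totals 3127 rose and 10106 fell, so that 23.6% of the calls were rises against 47.4% under TMM scaling.

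Of 34 genes of stressed and hyperproliferative keratinocytes, 31 rose, 2 fell and 1 did not pass, with a median log2 change of 7.26 (camera adjusted p = 1.1e-10; adjusted p = 0.21 with an estimated correlation). Largest were the cornified envelope precursors Sprr2b (11.86) and Sprr2a1 (11.1), the protease inhibitors Stfa2 (11.92), BC100530 (11.86) and Stfa1 (10.56), and Krt6b (10.19). Sprr2a3, which is not on this list, rose by 11.43. Members of the Sprr2, Stfa and Krt6 families have near-identical copies, so the split between copies is uncertain. All 30 proliferation genes rose, with a median of 1.78 (camera adjusted p = 1.1e-10; adjusted p = 0.35 with an estimated correlation), among them the mitotic kinase Aurka (2.67) and Mcm5 of the replicative helicase (2.14). Of 31 cornified envelope and barrier genes 22 rose and 8 fell, with a median of 1.64 (camera adjusted p = 0.00012; adjusted p = 0.29 with an estimated correlation). Rptn rose by 7.77, the desquamation protease Klk7 by 3.1, Lor by 1.23 and Ivl by 1.14. Of 26 hair follicle genes 14 rose and 2 fell, with a median of 1.89 (camera adjusted p = 0.013; adjusted p = 0.62 with an estimated correlation). Tchh, a protein of the inner root sheath, rose by 7.96 and the transcription factor Hoxc13 by 4.5. Krt36, a hair and nail keratin, was at 0 in every SPF ethanol library and at 105 ± 118 CPM with MC903, at least 5440-fold higher against a floor of 3 counts over the group. Without SPF MC903 1, at 242 CPM, the mean was 36.8 CPM and the bound 1900-fold. Its adjusted p was 0.062 in limma voom and ran from 1.8e-19 to 0.14 over the alternatives.

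Antimicrobial genes rose in SPF skin, 20 of 26 against 4 that fell, with a median of 1.75 (camera adjusted p = 0.00079; adjusted p = 0.083 with an estimated correlation). The defensins Defb4 and Defb1 rose by 8.6 and 3.34, the protease inhibitor Slpi by 7.42, and S100a8 and S100a9, which form calprotectin, by 5.32 and 5.79. Defb6 fell, with a log2 change of -4.12. Near-identical copies leave the defensin values uncertain. In the IL-17, IL-22 and IL-1 axis 12 of 18 genes rose and 4 fell, with a median of 0.99 (camera adjusted p = 0.042; adjusted p = 0.21 with an estimated correlation). The cytokine Il1b rose by 5.03. Il24, of the IL-20 family, was at 0 in SPF ethanol libraries and at 9.4 ± 2.35 CPM with MC903, at least 487-fold higher. Macrophage and monocyte markers rose in 15 of 20 cases and fell in 3, with a median of 0.96 (camera adjusted p = 0.021; adjusted p = 0.62 with an estimated correlation), among them Arg1 (2.49) and Itgam (1.75). Of 17 immediate early and heat shock genes 11 rose and 4 fell, with a median of 0.97 (camera adjusted p = 0.019; adjusted p = 0.51 with an estimated correlation), and Junb rose by 2.7. Without SPF MC903 3 the IL-17 axis and macrophage lists each had a camera adjusted p of 0.05, and with the length trend removed 0.09 and 0.16. The IL-17 axis then had a median of 0.89 (SE 1.24) against 0.99 (SE 1.27) before, and the macrophage list 0.52 (SE 0.33) against 0.96 (SE 0.35). Over the alternatives these ran from 0.034 to 0.21 and from 0.0092 to 0.62.

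Genes that fell with MC903 in SPF skin included Serpina3j (-9.38), Serpina3b (-7.79), the differentiation keratin Krt24 (-5.97), Cyp2g1 (-5.95), Skint4 (-5.04) and Mesp2 (-4.52). The Serpina3 and Skint families hold near-identical copies. Kctd12 was at 76.9 ± 63.3 CPM with ethanol and at 0 with MC903, at least 2800-fold lower, with an adjusted p of 0.28 in limma voom and from 7.3e-18 to 0.28 over the alternatives. It counted as a switching gene, at 104, 122 and 4.56 CPM in SPF ethanol 1, 2 and 3. Of 16 circadian clock genes 14 fell and 1 rose, with a median of -1.55 (camera adjusted p = 0.00044; adjusted p = 0.21 with an estimated correlation). The clock output factor Hlf changed by -3.6 and Per3 by -2.41. Of 18 T cell markers 11 fell and 1 rose, with a median of -0.83 (camera adjusted p = 0.0495; adjusted p = 0.21 with an estimated correlation). Cd3g, of the T cell receptor complex, changed by -1.79 and Il2rb by -1.28. The T cell call ended, at adjusted p from 0.05 to 0.062, without any 1 library other than SPF ethanol 2, SPF ethanol 3 or SPF MC903 1, and at 0.05 without switching genes, with 0.02 to 0.21 over the alternatives. Of 14 Schwann cell genes 12 fell, with a median of -0.86 (camera adjusted p = 0.0014; adjusted p = 0.29 with an estimated correlation), among them Ngfr (-2.85). Of 19 skeletal muscle genes 17 fell, with a median of -0.54 (camera adjusted p = 7e-04; adjusted p = 0.35 with an estimated correlation), among them Myh1 (-1.3) and Acta1 (-0.7).

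Lists whose set test did not pass in SPF skin also held single genes that changed. Among 15 tested type 2 genes 7 rose and 5 fell, with a median of 0.51 (adjusted p = 0.37). The alarmin Il33 (ID 77125, chromosome 19, 29925113 to 29960718) rose by 1.59, the growth factor Areg by 8.21 and the receptor gene Il4ra by 1.88, while Gata3 fell with a change of -2.01. Il4 summed to 5 counts with ethanol and 9 with MC903, Il13 to 4 and 25, Reg3g to 0 and 3, and Il31 and Il17a to 0 in both. These genes lay below the filter, so no change in them was tested. Among 14 vitamin D genes 6 rose and 3 fell. The calcium-binding protein gene S100g went from 0.00633 ± 0.011 to 10.4 ± 2.5 CPM (adjusted p = 3.2e-09), and Cyp27a1 changed by -2.31. The list's median was -0.01, against a mean of 1.39 (adjusted p = 0.54). Of 16 neutrophil genes 10 rose and 3 fell, and adjusted over the list alone 11 rose, with a median of 2.15 (adjusted p = 0.089). For every other list in SPF skin, the counts adjusted over the list alone equalled those over all genes tested. Among 17 chemokine genes 7 rose, including Ccl7 (4), and 4 fell, with a median of 0.35 (adjusted p = 0.7). Ccl17 and Ccl24 had changes of -0.52 (adjusted p = 0.28) and -0.01 (adjusted p = 0.99), and Ccl17 had -1.09 (adjusted p = 0.028) on library totals and -1.36 (adjusted p = 0.0098) with the length trend removed, within a range of 0.0098 to 0.78 over the alternatives. Retnla had 0.47 (adjusted p = 0.5). Among 15 basophil and mast cell genes 6 rose and 6 fell, with a median of -0.11 and a mean of 0.51 (adjusted p = 0.81). The basophil protease gene Mcpt8 went from 0.0186 ± 0.0184 to 2.22 ± 0.757 CPM (adjusted p = 6.3e-07).

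In the remaining lists of SPF skin the set tests had adjusted p of 0.17 or more. Ceramide genes rose in 18 of 33 cases and fell in 11 (median 0.36), and sebaceous genes fell in 15 of 24 and rose in 6 (median -0.39). Fibroblast and matrix genes rose in 10 of 26 cases, including the collagenase Mmp13 (8.47) and its inhibitor Timp1 (3.13), and fell in 14. That list's median of -0.3 and test were negative and its mean of 0.51 positive. Interferon genes rose in 7 of 30 cases and fell in 11 (median -0.09), and dendritic cell genes rose in 4 of 20 and fell in 6 (median -0.1). Endothelial genes rose in 3 of 16 cases and fell in 6, with a median of 0.07 and a mean of -0.16. Adipocyte genes fell in 7 of 15 cases and rose in 1 (median -0.33), and cartilage genes fell in 7 of 13 and rose in 2 (median -0.27). Of 9 aryl hydrocarbon receptor targets 3 rose and 4 fell (median -0.19), of 6 B cell genes 2 rose and 1 fell (median 0.64), and of 8 melanocyte genes 1 rose (median 0.01). Among 2 eosinophil genes and 4 red blood cell genes, 1 each rose. Shorter genes rose more often. Among the shortest decile of genes 56.3% rose and 13.5% fell, and among the longest decile 13.8% rose and 65.1% fell.

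In GF skin MC903 raised the same 4 genes, Tslp, Cyp24a1, Krt6a and Krt16. Tslp rose from 2.51 ± 1.05 to 996 ± 137 CPM (SD, n = 3), a log2 change of 8.63 (SE 0.25, adjusted p = 2.5e-10). Cyp24a1 rose from 64.5 ± 16.9 to 4077 ± 417 CPM (log2 change 5.98, adjusted p = 6.8e-08), Krt6a from 111 ± 25.5 to 3730 ± 383 CPM (5.07, adjusted p = 1.3e-09) and Krt16 from 33.8 ± 22.6 to 8691 ± 628 CPM (8.01, adjusted p = 5.6e-08). Of 16466 genes 11274 changed, 5497 up and 5777 down, and 4175 of them by at least 2-fold. On library totals 2795 rose and 9697 fell, or 22.4% rises against 48.8% under TMM scaling. Il33 rose by 0.83 (adjusted p = 0.00036, and from 4.7e-08 to 0.23 over the alternatives, with a change of 0.32 and adjusted p = 0.091 on library totals), Areg by 6.29 and Il4ra by 1.56. S100g rose by 8.61.

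Stress keratinocyte genes rose in 31 of 34 cases in GF skin, with a median of 5.95 (camera adjusted p = 1.3e-12; adjusted p = 0.2 with an estimated correlation). Sprr2b (10.16), Stfa2 (10.1), Sprr2a1 (9.73), BC100530 (8.76) and Stfa1 (8.74) led the list. Sprr2a3, which is not on it, rose by 9.05. Krt36, of the hair follicle list, rose by 12.12, from a mean of 0.103 to 473 CPM. Its ethanol values were 0.14, 0 and 0.168 CPM, so the size of that rise is uncertain. All 30 proliferation genes rose, with a median of 1.76 (camera adjusted p = 8.7e-13; adjusted p = 0.26 with an estimated correlation), including the mitotic kinases Plk1 (2.86) and Aurka (2.32). Cornified envelope genes rose in 23 of 31 cases and fell in 6, with a median of 1.43 (camera adjusted p = 1.6e-05; adjusted p = 0.25 with an estimated correlation). Klk7 rose by 2.41 and Lor by 1.26. Ivl rose by 0.38 (adjusted p = 0.0053) under TMM scaling and had a change of -0.14 (adjusted p = 0.21) on library totals, with adjusted p from 0.00065 to 0.21 over the alternatives. Hair follicle genes rose in 15 of 26 cases and fell in 2, with a median of 1.42 (camera adjusted p = 0.00072; adjusted p = 0.42 with an estimated correlation), among them Tchh (6.72) and Hoxc13 (3.8). Antimicrobial genes rose in 17 of 26 cases and fell in 4, with a median of 1.31 (camera adjusted p = 0.00055; adjusted p = 0.073 with an estimated correlation). Defb4 rose by 7.85, Slpi by 6.81, S100a8 by 6.08 and S100a9 by 5.55. The IL-17 axis had 13 rises and 4 falls among 18 genes, with a median of 0.92 (camera adjusted p = 0.01; adjusted p = 0.19 with an estimated correlation), and Il19 (7.98) and Il1b (4.19) rose. Neutrophil genes rose in 12 of 16 cases and fell in 2, with a median of 2.07 (camera adjusted p = 0.044; adjusted p = 0.26 with an estimated correlation), among them the attractant Cxcl1 (3.22). The neutrophil call ended without SPF MC903 2, SPF MC903 3, GF MC903 1 or GF ethanol 4, at adjusted p from 0.052 to 0.07, and at 0.1 with the length trend removed, with 0.024 to 0.26 over the alternatives. With the trend removed its median was 2.08 (SE 0.7), against 2.07 (SE 0.72) before.

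Clock genes fell in 14 of 16 cases in GF skin and 1 rose, with a median of -0.8 (camera adjusted p = 0.001; adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone 15 clock genes fell, and the counts for other called lists were unchanged. Hlf changed by -1.44 and Per3 by -1.62. Schwann cell genes fell in 13 of 14 cases, with a median of -0.88 (camera adjusted p = 0.00024; adjusted p = 0.25 with an estimated correlation), including Ngfr (-2.56) and Mal (-1.65). Muscle genes fell in 15 of 19 cases, with a median of -0.53 (camera adjusted p = 0.00025; adjusted p = 0.26 with an estimated correlation), including Myl1 (-1.04) and Acta1 (-0.8). Cartilage genes fell in 11 of 13 cases, with a median of -0.45 (camera adjusted p = 0.013; adjusted p = 0.26 with an estimated correlation), including Col9a1 (-1.24) and Hapln1 (-1.08). Serpina3j (-6.78), Cyp2g1 (-4.49) and Serpina3b (-4.38) fell. T cell markers fell in 6 of 18 cases, including Cd247 (-1.04), and rose in 2, Icos (1.61) and Thy1 (0.86), with a median of -0.23 (adjusted p = 0.54). Macrophage genes rose in 14 of 20 cases and fell in 4 (median 0.75, adjusted p = 0.06, past the threshold without SPF ethanol 1 or GF MC903 4, with 0.043 to 0.62 over the alternatives), and interferon genes rose in 13 of 30 and fell in 6 (median 0.39, adjusted p = 0.38). Basophil genes had a median of -0.12 with a mean of 0.36, and fibroblast genes a median of -0.43 with a mean of 0.25. Mcpt8 rose by 4.98, the basophil protease Prss34 by 3.79 and Mmp13 by 8.59. Ccl17 (0.1, adjusted p = 0.83), Ccl24 (0.67, adjusted p = 0.1) and Retnla (0.4, adjusted p = 0.48) did not pass, though Ccl24 had 0.024 without SPF ethanol 1, within 0.024 to 0.69 over the alternatives. With the length trend removed Ccl17 had -0.88 (adjusted p = 0.045), the lowest p of its alternatives, which ran up to 1. Il4 summed to 22 counts with ethanol and 13 with MC903, Il13 to 9 and 20, Reg3g to 0 and 10, Il17a to 0 and 2, and Il31 to 0 in both.

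Adnp and Akap2, among the largest falls in GF skin, lie in loci where the annotation holds a second gene model. Adnp fell from 102 to 0.16 CPM (log2 change -9.28), while the gene model Dpm1-adnp, outside the rule and chosen after its values were seen, went from a mean of 3.68 to 68.1 CPM. Its ethanol mean rested on GF ethanol 5 at 11 CPM, with 0 in GF ethanol 1 and 4. Dpm1-adnp was at 98.5 and 105 CPM in GF MC903 1 and 4 and at 0.315 CPM in GF MC903 5, where Adnp was at 0.201 CPM, so both were near 0 in that library. Akap2 was at 17.4 ± 9.97 CPM with ethanol and at 0 with MC903, at least 614-fold lower, while the gene model Pakap, chosen in the same way, went from 7.7 to 15.6 CPM. Pakap was at 1, 4.35 and 17.7 CPM in GF ethanol 1, 4 and 5. In GF MC903 1, 4 and 5 it was at 7.13, 23 and 16.8 CPM, so the groups overlapped. Elmod2 (-5.48), Tcf12 (-4.93) and Ablim1 (-4.35) also fell. Limma voom gave adjusted p of 0.23 for Adnp (5.6e-12 to 0.23 over the alternatives) and 0.075 for Ablim1 (0.00015 to 0.78). Among the shortest decile of genes 60.8% rose with MC903 in GF skin and 8.5% fell, and among the longest decile 11.5% rose and 62.4% fell.

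**Figure D1:**
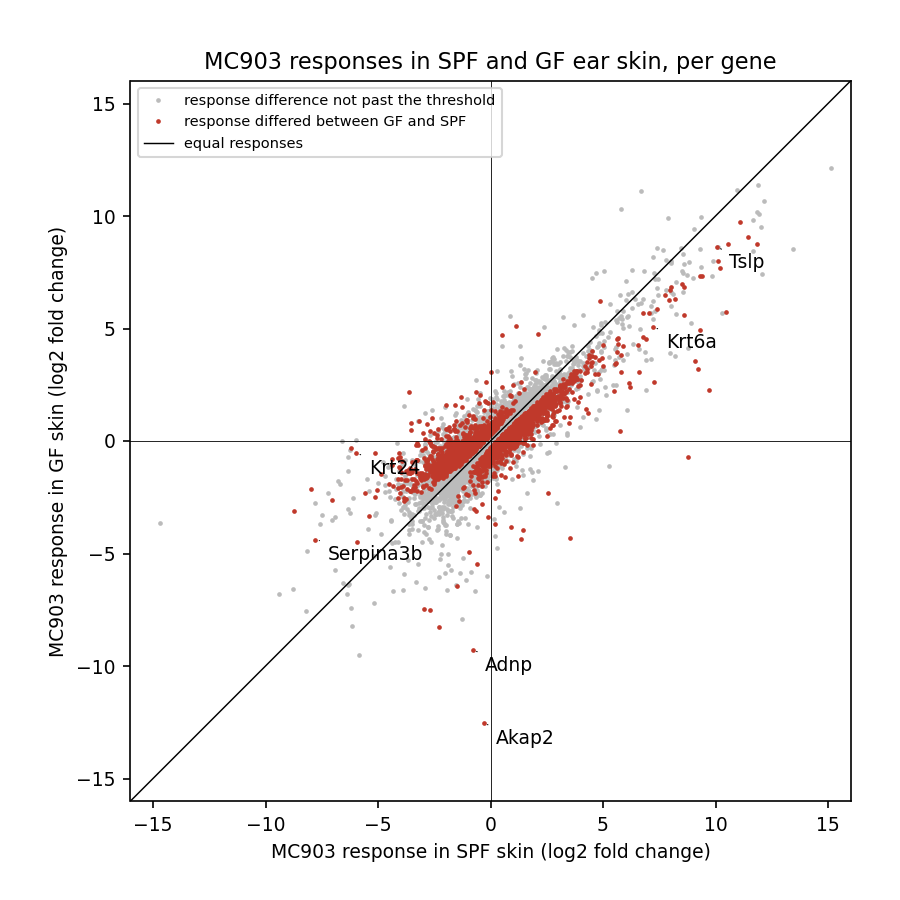
Log2 fold change with MC903 in GF skin (vertical axis) against SPF skin (horizontal axis) for 16466 genes, 3 libraries per group, with the 2800 genes whose responses differed in red. The regression of GF on SPF has a slope of 0.73, and Krt24 lies far above it.

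The response in GF skin followed that in SPF skin. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.86 (jackknife SE 0.029) and a Spearman correlation of 0.88, with a slope of GF on SPF of 0.73 (SE 0.062) and of SPF on GF of 1.02. A slope also falls with imperfect correlation, and the SDs of the log2 changes, 1.23 in GF and 1.46 in SPF skin, had a ratio of 0.85 (SE 0.078). The genes that rose in both numbered 4851 against 1921 for independent lists, and those that fell in both 4953 against 2243. Another 111 moved in opposite directions. Genes that rose in SPF skin had a median of 0.91 there and 0.73 in GF skin, and those that fell had -0.98 and -0.71. Chosen by their GF call, rising genes had a median of 0.79 in GF and 0.89 in SPF skin, and falling genes -0.81 and -0.91. The responses differed in 2800 genes, 1276 more positive and 1524 more negative in GF skin, and 639 of them by at least 2-fold. On library totals 1656 were more positive and 1151 more negative, or 59% against 45.6%. Of 2187 differing genes that changed in GF skin, the response was smaller in 1672, larger in 242 and opposite in 273.

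Tslp and many stress keratinocyte genes rose less in GF skin. Their difference in log2 change was -1.42 for Tslp (SE 0.28, adjusted p = 0.0052), -2.16 for Krt6a (SE 0.23, adjusted p = 0.00012), -2.11 for Krt16 (adjusted p = 0.02), -1.09 for Krt17 and -0.88 for Sprr1a. Stress keratinocyte genes were more negative in 14 of 34 cases and more positive in 3, with a median of -1.13 (camera adjusted p = 0.00023; adjusted p = 0.66 with an estimated correlation). Adjusted over the list alone, 17 were more negative. Part of these differences lay in ethanol skin. The stress list had a median of 0.4 between ethanol groups (camera adjusted p = 0.04) and -0.46 between MC903 groups (camera adjusted p = 0.076). Krt16 had 573 to 2704 counts in GF and 442 to 549 in SPF ethanol libraries. With MC903 its counts, not scaled for depth, were 287859 to 322132 in GF and 301604 to 481348 in SPF libraries. The lowest SPF count was that of SPF MC903 3, which had the lowest total of all libraries (36358294). These ranges therefore do not show an overlap at equal depth. Cornified envelope genes were more negative in 12 of 31 cases and more positive in 3, and adjusted over the list alone in 13 and 4, with a median of -0.25 (camera adjusted p = 0.0043; adjusted p = 0.66 with an estimated correlation). Among them were the crosslinking enzyme Tgm3 (-1.85), the protease inhibitor Spink5 (-1.15), Ivl (-0.77, adjusted p = 0.0035) and, more positive, Krt2 (2.73), a keratin of the upper epidermis. Lor had a difference of 0.03 (adjusted p = 0.95). Immediate early genes were more negative in 11 of 17 cases and more positive in 1, also when adjusted over the list alone, with a median of -0.53 (camera adjusted p = 0.00077; adjusted p = 0.59 with an estimated correlation), including Fos (-1.34), the chaperone Hsp90aa1 (-0.57) and, more positive, Egr2 (0.78). This list too differed in ethanol skin, with a median of 0.26 for GF minus SPF (camera adjusted p = 0.0024). Between MC903 groups it was not called, with a median of -0.22 (camera adjusted p = 0.3). Il33 (-0.76, adjusted p = 0.029), Areg (-1.92, adjusted p = 0.034), the calcium pump Atp2b1 (-1.12), Arg1 (-1.55), Itgam (-0.93) and Defb1 (-1.14) were also more negative. Cyp24a1 had -1.16 (adjusted p = 0.099, and 0.039 without SPF ethanol 3, within 0.039 to 0.22 over the alternatives), Il1b -0.84 (adjusted p = 0.35), S100a8 0.76 (adjusted p = 0.44) and S100a9 -0.24 (adjusted p = 0.81).

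The Krt16 call ended without SPF ethanol 3 (adjusted p = 0.05) and in limma voom (0.052), with 0.00041 to 0.052 over the alternatives. The Il33 call ended without SPF ethanol 1 or 2, SPF MC903 1 or 3, GF MC903 4 or GF ethanol 5, at adjusted p from 0.06 to 0.072, and on library totals (0.053), with 0.0019 to 0.072 over the alternatives. The Areg call ended without SPF ethanol 1 or 2, SPF MC903 2 or 3, GF MC903 1 or 4, or GF ethanol 4 or 5, at adjusted p from 0.054 to 0.11, and in limma voom (0.3), with 0.011 to 0.3 over the alternatives. Ccl17 (0.61, adjusted p = 0.5), Ccl24 (0.67, adjusted p = 0.41) and Retnla (-0.07, adjusted p = 0.97) did not pass.

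Krt24 kept most of its level in GF skin. Krt24 (ID 75706, chromosome 11, 99279959 to 99285262) went from 310 ± 42.7 to 4.96 ± 0.578 CPM with MC903 in SPF skin and from 333 ± 29.4 to 231 ± 36.6 CPM in GF skin (SD, n = 3), a difference of 5.44 (SE 0.2, adjusted p = 3.5e-08). Other genes with a more positive response in GF skin were Mt4 (3.57), Serpina3b (3.41), Defb6 (3.38), Olig1 (3.36), Alox12e (3.2), Slurp2 (3.06), Scgb1b27 (3.03) and Gata3 (1.42). T cell markers were more positive in 6 of 18 cases, and adjusted over the list alone in 8, with a median of 0.53 (camera adjusted p = 0.00077; adjusted p = 0.086 with an estimated correlation), including Cd3g (1.37) and Cd3e (1.05). Clock genes were more positive in 7 of 16 cases and more negative in 1, and adjusted over the list alone in 10 and 1, with a median of 0.61 (camera adjusted p = 0.00023; adjusted p = 0.34 with an estimated correlation), including Hlf (2.16) and Tef (0.71). Interferon genes were more positive in 3 of 30 cases, and adjusted over the list alone in 2, with a median of 0.35 (camera adjusted p = 0.027; adjusted p = 0.71 with an estimated correlation). These were Xaf1 (0.91), Stat2 (0.69) and the chemokine gene Cxcl10 (1.9). The list's call ended without SPF ethanol 1, SPF MC903 2, GF ethanol 4 or GF MC903 5, at adjusted p from 0.068 to 0.15, with 0.0057 to 0.71 over the alternatives. Stat2 lost its call without any 1 library other than SPF MC903 1 or GF ethanol 1 (0.052 to 0.099), with no expression filter (0.059) and with the length trend removed (0.051, at 0.67), with 0.012 to 0.099 over the alternatives. Cxcl10 lost it without SPF ethanol 2, GF ethanol 1 or 5, or GF MC903 5 (0.054 to 0.06).

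Proliferation genes had a median difference of 0.06 (adjusted p = 0.75, and 0.037 without GF ethanol 4, within 0.037 to 0.96 over the alternatives), with Mki67 (0.68) and Mcm7 (0.38) more positive, Mcm5 (-0.47) more negative and 27 that did not pass. Mki67 lost its call without SPF MC903 2 or 3, SPF ethanol 3, GF ethanol 1 or 5, or GF MC903 1, 4 or 5, at adjusted p from 0.05 to 0.067, and with the length trend removed (0.11, at 0.53), the lowest being 0.0061. Mcm7 lost it without SPF ethanol 1, 2 or 3, SPF MC903 3, GF ethanol 1 or 5, or GF MC903 1 or 5 (0.059 to 0.087), with DESeq2 size factors (0.051) and with no expression filter (0.056), the lowest being 0.013, and Mcm5 without GF ethanol 4 or GF MC903 4 (0.05 to 0.054). Muscle genes had a median difference of 0.01. Vitamin D genes had a median of -0.01 and a mean of -0.18 with a test in the other direction, B cell genes a median of 0.11 and a mean of 0.35 with a negative test, and antimicrobial genes a median of -0.14 and a mean of 0.02.

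The most negative differences in this comparison were those of Akap2 (-12.24), Adnp (-8.49), Ablim1 (-5.7), Elmod2 (-4.86), Ankrd49 (-4.72), Sprr2a2 (-4.39), Tcf12 (-3.97) and Camsap2 (-3.86). Akap2 was at 0 in all GF MC903 libraries, so its value depends on the prior count. The Ablim1 call ended without SPF ethanol 3 or GF MC903 4 (adjusted p = 0.05), that of Sprr2a2 without SPF ethanol 1 or 2 (0.051 to 0.053), and that of Camsap2 without SPF ethanol 1 or 2, GF ethanol 1 or 4, or GF MC903 1, 4 or 5 (0.052 to 0.061). Limma voom gave the highest adjusted p of the alternatives for 5 of them. Over the alternatives these ran from 1.8e-10 to 0.63 for Adnp, from 5.8e-14 to 0.059 for Akap2, from 0.0021 to 0.13 for Ablim1, from 0.0014 to 0.1 for Sprr2a2 and from 0.006 to 0.17 for Camsap2.

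**Figure D2:**
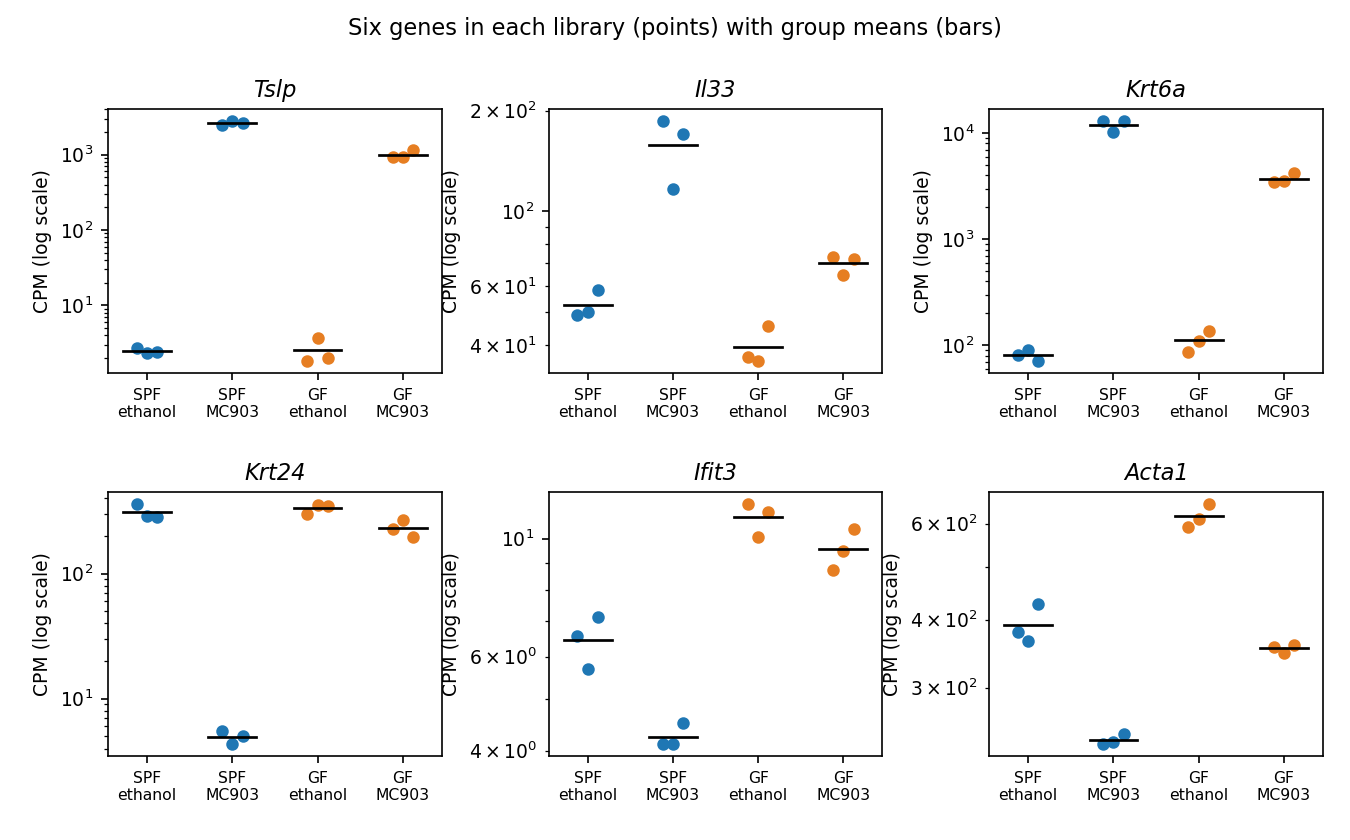
CPM per library on a log axis for Tslp, Il33, Krt6a, Krt24, Ifit3 and Acta1 in the 4 groups of 3 libraries, with bars at group means. Krt24 fell to 4.96 CPM with MC903 in SPF skin and was at 231 CPM in GF skin.

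Between ethanol groups, GF skin held more transcripts of Acta1, Ifit3 and H2-Ab1. Acta1 (ID 11459, chromosome 8, 123891758 to 123894775), the actin of skeletal muscle, was at 619 ± 30.3 CPM in GF and 391 ± 32.5 in SPF skin (SD, n = 3), a log2 difference of 0.66 (SE 0.065, adjusted p = 0.00023). Ifit3 (ID 15959, chromosome 19, 34583119 to 34588982), an interferon-induced gene, was at 11 ± 0.799 against 6.46 ± 0.72 CPM (0.76, adjusted p = 0.0015). H2-Ab1 (ID 14961, chromosome 17, 34263227 to 34269418), of MHC class II, was at 389 ± 29.6 against 245 ± 30.6 CPM (0.67, adjusted p = 0.0012). Of 16466 genes 3616 differed, 1914 higher and 1702 lower in GF skin, 300 of them by at least 2-fold. On library totals 1420 were higher and 2218 lower, or 39% higher against 52.9%, and with the length trend removed 2300 differed, 1473 higher and 827 lower. The count was 2369 without SPF ethanol 2, 2346 without SPF ethanol 3 and 1511 without GF ethanol 4.

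Muscle genes were higher in GF ethanol skin in 17 of 19 cases, also when adjusted over the list alone, with a median of 0.7 (camera adjusted p = 1.3e-15; adjusted p = 0.12 with an estimated correlation). Pvalb (1.15) was among them, and the slow muscle genes Myl2 (2.44) and Myh7 (1.97) were higher too. The list's mean log2 CPM lay between 7 and 7.07 in GF and between 6.21 and 6.46 in SPF ethanol libraries, and with it as a covariate edgeR called 0 genes, with 681 at an unadjusted p under 0.05. Interferon genes were higher in 15 of 30 cases, and adjusted over the list alone in 18, with a median of 0.81 (camera adjusted p = 1.9e-07; adjusted p = 0.2 with an estimated correlation), including Oasl2 (1.96) and Oas1a (1.82). Dendritic cell genes were higher in 12 of 20 cases, and adjusted over the list alone in 14, with a median of 0.64 (camera adjusted p = 1.8e-06; adjusted p = 0.36 with an estimated correlation), including Cd74 (0.72), the MHC class II invariant chain. Chemokine genes were higher in 5 of 17 cases, and adjusted over the list alone in 6, with a median of 0.74 (camera adjusted p = 0.007; adjusted p = 0.26 with an estimated correlation). These included Ccl27a (1.3), Ccl22 (1.14), Ccl17 (1.24, adjusted p = 0.036) and Ccl24 (1.09, adjusted p = 0.046). Alox15 (1.8) and Ear2 (0.86), the 2 tested genes of the eosinophil list, and Retnla (2.35, adjusted p = 0.012) were also higher. The rest of the 10 genes on that list fell below the filter, so it says little about eosinophils. Leaving out GF ethanol 4 ended the calls of Ccl22 (adjusted p = 0.053), Retnla (0.051), Alox15 and Ccl17. Alox15 also lost it without SPF ethanol 3 (0.055 to 0.073 for both), and Ccl17 without SPF ethanol 1 or 3 or GF ethanol 1 (0.068 to 0.11) and with the length trend removed (0.083, at 1.03), with 0.0071 to 0.97 over the alternatives. Ccl24 lost its call without any 1 library other than SPF ethanol 1, GF MC903 1 or GF MC903 5 (0.051 to 0.15), on library totals (0.059), with no expression filter (0.053) and with the length trend removed (0.087, at 0.95), with 0.0054 to 1 over the alternatives. Ear2 lost it without any 1 library other than SPF ethanol 1, SPF MC903 3 or GF ethanol 5 (0.05 to 0.16), on library totals (0.061), with no expression filter (0.053), in limma voom (0.051), with only the libraries compared (0.077) and with the length trend removed (0.12, at 0.67), with 0.022 to 0.97 over the alternatives. The muscle covariate ended every gene's call in this comparison.

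Cartilage genes were higher in GF ethanol skin in 6 of 13 cases, with a median of 0.41 (camera adjusted p = 0.0024; adjusted p = 0.26 with an estimated correlation), including Comp (1.19) and Cytl1 (1.06). Adjusted over the list alone 6 were higher and 1 lower. Immediate early genes were higher in 6 of 17 cases, and adjusted over the list alone 9 were higher and 1 lower, with a median of 0.26 (camera adjusted p = 0.0024; adjusted p = 0.45 with an estimated correlation). Endothelial genes were higher in 4 of 16 cases, also when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.015; adjusted p = 0.2 with an estimated correlation). Sebaceous genes were lower in 7 of 24 cases and higher in 2, and adjusted over the list alone in 11 and 3, with a median of -0.23 (camera adjusted p = 0.0032; adjusted p = 0.55 with an estimated correlation), including the sterol enzyme Hmgcs1 (-0.37) and Far2 (-0.42). Stress keratinocyte genes were higher in 7 of 34 cases and lower in 1, and adjusted over the list alone in 11 and 1, with a median of 0.4 (camera adjusted p = 0.04; adjusted p = 0.82 with an estimated correlation). Of its genes BC100530 (2.66), Sprr2f (1.95) and Krt16 (1.81, adjusted p = 0.0092) were higher, as was Sprr2a3 (2.55), which is not on the list. Limma voom gave adjusted p of 0.099 for BC100530 (0.00014 to 0.97 over the alternatives) and 0.23 for Sprr2f (2e-04 to 0.97). The stress list's call ended without SPF MC903 1, 2 or 3 or GF ethanol 4 or 5, at adjusted p from 0.056 to 0.43, and with the length trend removed (0.48, at a median of 0.2 with SE 0.19, against 0.4 with SE 0.19 before), with 3.1e-06 to 0.82 over the alternatives. Hair follicle genes were higher in 4 of 26 cases, and adjusted over the list alone in 2, with a median of 0.68 (camera adjusted p = 0.013; adjusted p = 0.81 with an estimated correlation), a call that ended without SPF ethanol 3 or GF ethanol 1 (0.053 to 0.22).

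Among single genes between ethanol groups, Ugt1a6b was higher in GF skin (2.9) and its neighbour Ugt1a6a, with which it shares exons, lower (-1). The gut hormone gene Pyy was higher by 2.12. Erdr1 (-5.68), Sptssb (-2.4), Gpr137b-ps (-2.07), Cd163l1 (-1.78), Lmbrd2 (-1.61), Tmprss11e (-1.56), Lrrc8b (-1.53) and Sned1 (-1.5) were lower. Tslp (0.03, adjusted p = 0.95), Cyp24a1 (-0.03, adjusted p = 0.97), S100a8 (-0.04, adjusted p = 0.96), S100a9 (0.83, adjusted p = 0.2), Il1b (0.61, adjusted p = 0.39), Il33 (-0.41, adjusted p = 0.069), Krt6a (0.47, adjusted p = 0.056), Lor (0.36, adjusted p = 0.12) and Ivl (0.28, adjusted p = 0.066) did not pass. Over the alternatives the adjusted p ran from 0.015 to 0.97 for Il33, from 0.0089 to 0.97 for Krt6a, from 0.05 to 0.97 for Lor and from 0.018 to 1 for Ivl. Il33 passed without SPF MC903 2 (0.015) or GF ethanol 5 (0.043), Krt6a without SPF MC903 2 (0.045) or GF ethanol 1 (0.021), and Ivl without SPF ethanol 3 (0.037) or GF ethanol 5 (0.018). Proliferation genes had a median of 0.07 and T cell genes a median of 0.05. The median and mean had different signs in the type 2 (0.02, -0.03), vitamin D (-0.02, 0.22), basophil (-0.05, 0.17), ceramide (0.01, -0.01), fibroblast (-0.15, 0.05) and aryl hydrocarbon receptor lists (0.03, -0.11), and the clock list had -0.01 for both and a positive test. Differences followed gene length and, less strongly, GC content, the percent of G and C bases in a gene's longest transcript. Across genes the Spearman correlation was -0.4 with length and 0.27 with GC content between ethanol groups. Between MC903 groups these were -0.26 and 0.21. Only the length trend was removed in an alternative. Among the shortest decile of genes 25.6% were higher in GF skin and 1.5% lower, and among the longest decile 1.6% were higher and 33.3% lower.

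**Figure D3:**
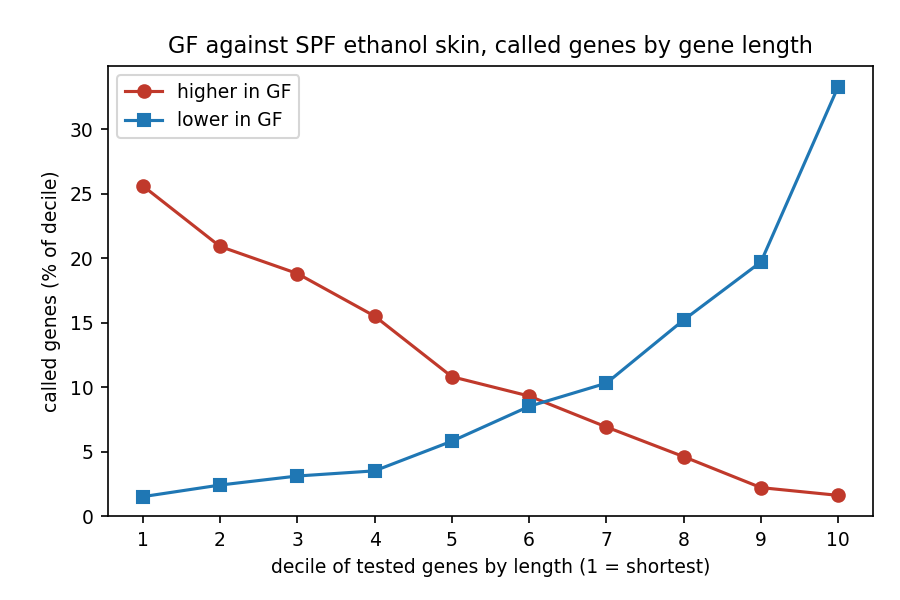
Percent of genes higher and lower in GF than in SPF ethanol skin (vertical axis) by decile of gene length (horizontal axis), 3 libraries per group. The share of genes higher in GF skin falls from 25.6% to 1.6% from the shortest to the longest decile.

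Under MC903, GF skin had less Tslp and Krt6a than SPF skin and more Krt24, Ifit1 and Cd3g. Tslp was lower by a log2 difference of -1.4 (SE 0.18, adjusted p = 7.4e-05), Krt6a by -1.69 (adjusted p = 1.1e-05), Il33 by -1.17 (adjusted p = 8.5e-05), Areg by -1.45 and Cyp24a1 by -1.19 (adjusted p = 0.01). Krt24 was higher by 5.54 (adjusted p = 2.1e-09). Of 16466 genes 6871 differed, 3431 higher and 3440 lower in GF skin, 1265 of them by at least 2-fold. Interferon genes were higher in 26 of 30 cases, with a median of 1.18 (camera adjusted p = 9.1e-09; adjusted p = 0.14 with an estimated correlation), with the same count adjusted over the list alone, including Ifit1 (2.12), Xaf1 (1.49), Bst2 (1.23) and Ifit3 (1.17). Muscle genes were higher in 18 of 19 cases, and adjusted over the list alone in 19, with a median of 0.7 (camera adjusted p = 1.3e-09; adjusted p = 0.14 with an estimated correlation), including Tcap (1.09) and Tnnt3 (0.89). With the muscle mean as a covariate edgeR called 1 gene, with 2116 at an unadjusted p under 0.05. Dendritic cell genes were higher in 12 of 20 cases, also when adjusted over the list alone, with a median of 0.64 (camera adjusted p = 0.00013; adjusted p = 0.6 with an estimated correlation), including Cd74 (1.09) and H2-Ab1 (0.94). T cell markers were higher in 9 of 18 cases, and adjusted over the list alone in 12, with a median of 0.66 (camera adjusted p = 0.00077; adjusted p = 0.086 with an estimated correlation), including Cd3g (1.48), Cd3e (1.25) and Thy1 (0.94). Clock genes were higher in 10 of 16 cases and lower in 2, and adjusted over the list alone in 11 and 2, with a median of 0.7 (camera adjusted p = 0.0024; adjusted p = 0.38 with an estimated correlation), including Hlf (2.21) and Dbp (2.04).

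**Figure D4:**
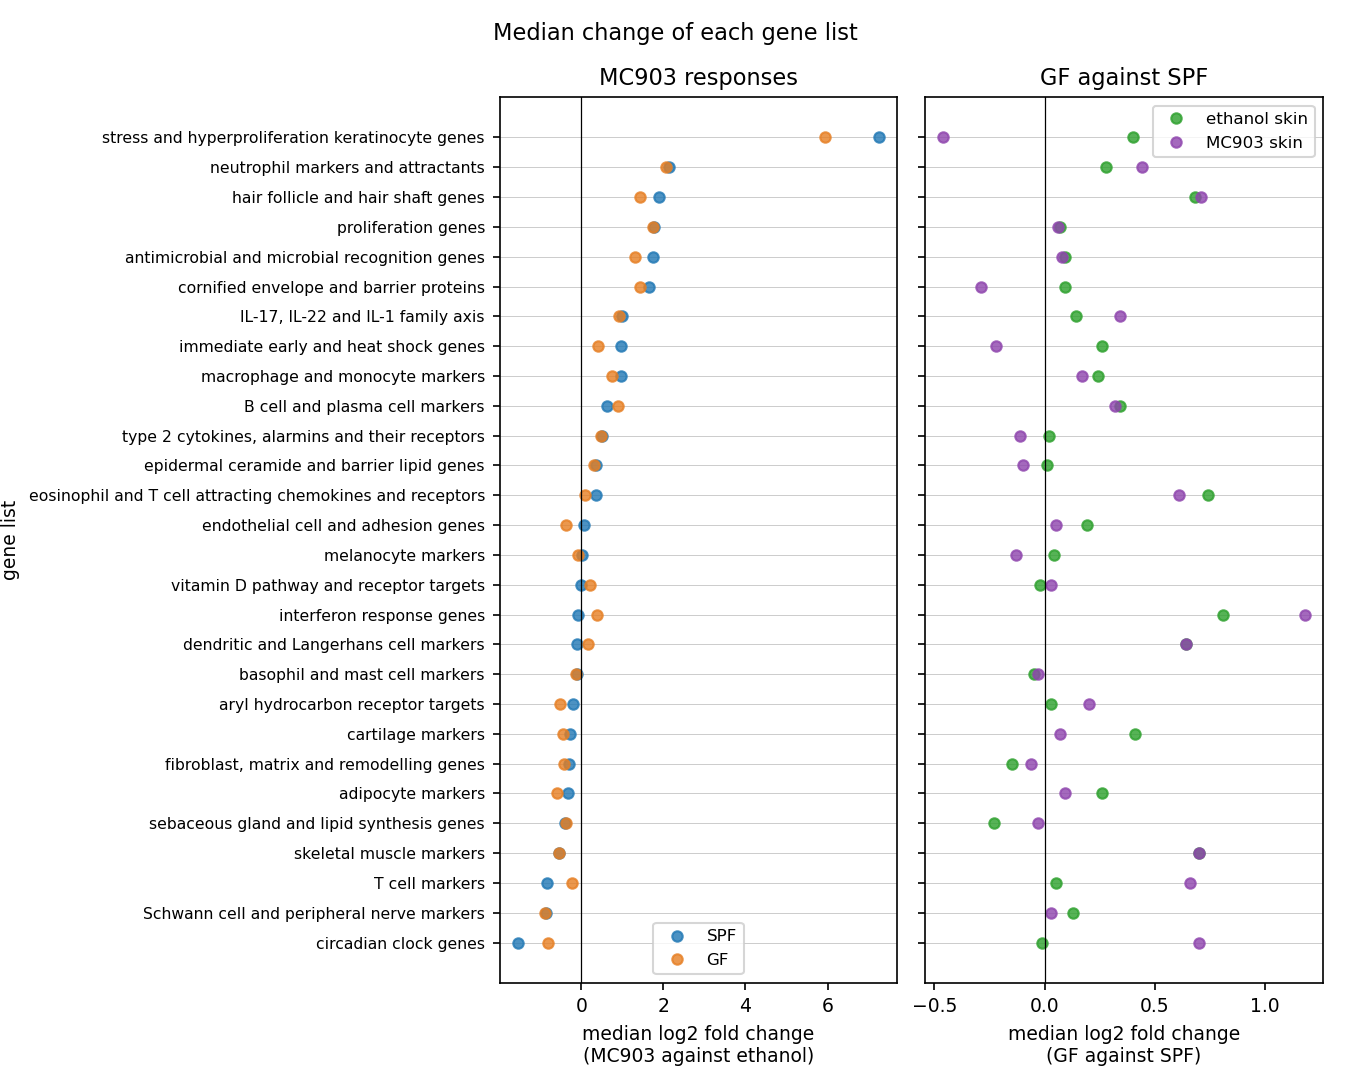
Median log2 fold change of each gene list with at least 5 tested genes, for the MC903 responses in SPF and GF skin in 1 panel and for GF minus SPF skin with ethanol and with MC903 in the other. Interferon genes have medians of 0.81 and 1.18 between housings, and stress keratinocyte genes medians of 7.26 and 5.95 with MC903.

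Stress keratinocyte genes were lower in GF MC903 skin in 14 of 34 cases and higher in 3, with a median of -0.46 (adjusted p = 0.076), and cornified envelope genes lower in 15 of 31 and higher in 6, or 8 adjusted over the list alone, with a median of -0.29 (adjusted p = 0.16). With the length trend removed the set tests of both passed, with 22 stress keratinocyte genes lower and a median of -0.81 (camera adjusted p = 0.0032, and 0.0032 to 0.94 over the alternatives), and a cornified envelope median of -0.28 (0.011, and 0.011 to 0.94). The stress list also passed without SPF ethanol 3, GF ethanol 1 or GF ethanol 5, and with an estimated correlation both had an adjusted p of 0.94. Sprr1a (-1.13), Arg1 (-1.52), Defb1 (-1.45) and Ivl (-0.49, adjusted p = 0.0021) were lower, and Krt2 (2.96), Serpina3b (4.18), Pyy (4.12), Alox12e (3.76), Defb6 (3.66), Olig1 (3.65), Fcgbp (3.5) and S100g (1.43) were higher. Ccl17 (1.85, adjusted p = 0.0032), Ccl24 (1.76, adjusted p = 0.0021), Retnla (2.28, adjusted p = 0.0055), Ear2 (1.91) and Alox15 (1.66) were higher, while the chemokine list, with 7 of 17 higher, had a median of 0.61, or 0.65 with genes at 0 set to their bound (adjusted p = 0.14). Krt16 (-0.3, adjusted p = 0.56), Il1b (-0.23, adjusted p = 0.57), S100a8 (0.71, adjusted p = 0.079), S100a9 (0.59, adjusted p = 0.14) and Lor (0.39, adjusted p = 0.069) did not pass, though S100a8 had adjusted p from 0.014 to 0.59 and Lor from 0.034 to 0.43 over the alternatives, with 0.023 for S100a8 without GF ethanol 5 and 0.036 for Lor without SPF MC903 2. Akap2 was at 0 in GF MC903 libraries, at least 607-fold lower than in SPF skin. Elmod2 (-5.12), Ablim1 (-4.85), Slc39a14 (-4.51), Tcf12 (-4.41), Ankrd49 (-4.32), Erdr1 (-4.31), Camsap2 (-3.88) and Ugt1a6a (-2.48) were lower. Rps27 (4.76, adjusted p = 0.011) rested on GF MC903 4 at 809 CPM, against 5.27 to 11.9 CPM in the others, and without that library had a log2 difference of 0.19 (adjusted p = 0.25). Slc39a14 had -2.18 (adjusted p = 0.097) without SPF MC903 1. Limma voom gave adjusted p of 0.27 for both, 0.076 for Ablim1 and 0.069 for Camsap2. Over the alternatives these ran from 0.0024 to 0.43 for Rps27, from 0.0044 to 0.86 for Slc39a14, from 4.5e-05 to 0.64 for Ablim1 and from 1.1e-05 to 0.29 for Camsap2. The median and mean had different signs in the basophil (-0.03, 0.01), sebaceous (-0.03, 0.06), Schwann cell (0.03, -0.06) and aryl hydrocarbon receptor lists (0.2, -0.14). Genes higher in GF skin under both treatments numbered 1118 against 399 for independent lists, those lower 942 against 356, and 174 differed in opposite directions. Among the shortest decile of genes 39% were higher in GF MC903 skin and 6.3% lower, and among the longest decile 11.4% were higher and 32.7% lower.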

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

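The tests of gene length, tissue share, dose, scaling, depth and switching genes below were chosen after the result was seen, and the splits of the libraries before. Where list medians weigh a cause, their SEs count genes as independent, so the values speak for or against it without settling it. The results in this part were singled out because the response to MC903 differed between GF and SPF skin by the interaction test, and each value is the GF minus the SPF response in log2. It differed in 2800 genes. More positive in GF skin were Krt24 (5.44), Mt4 (3.57), Serpina3b (3.41), Defb6 (3.38), Olig1 (3.36), Alox12e (3.2), Slurp2 (3.06), Scgb1b27 (3.03), Krt2 (2.73), Hlf (2.16), Cxcl10 (1.9), Gata3 (1.42), Cd3g (1.37), Cd3e (1.05), Xaf1 (0.91), Egr2 (0.78), Tef (0.71), Stat2 (0.69), Mki67 (0.68) and Mcm7 (0.38). More negative were Akap2 (-12.24), Adnp (-8.49), Ablim1 (-5.7), Elmod2 (-4.86), Ankrd49 (-4.72), Sprr2a2 (-4.39), Tcf12 (-3.97), Camsap2 (-3.86), Krt6a (-2.16), Krt16 (-2.11), Areg (-1.92), Tgm3 (-1.85), Arg1 (-1.55), Tslp (-1.42), Fos (-1.34), Spink5 (-1.15), Defb1 (-1.14), Atp2b1 (-1.12), Krt17 (-1.09), Itgam (-0.93), Sprr1a (-0.88), Ivl (-0.77), Il33 (-0.76), Hsp90aa1 (-0.57) and Mcm5 (-0.47). Among gene lists called by camera at its preset correlation the medians were 0.53 for T cell, 0.61 for clock and 0.35 for interferon genes, and -1.13 for stress keratinocyte, -0.53 for immediate early and -0.25 for cornified envelope genes. With an estimated correlation these 6 calls ended, at adjusted p = 0.086, 0.34, 0.71, 0.66, 0.59 and 0.66 in that order.

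The SD of the log2 changes was smaller in GF than in SPF skin, with a ratio of 0.85 (jackknife SE 0.078), and the slope was 0.73 of GF on SPF and 1.02 of SPF on GF. Different scaling would shift rising and falling genes in opposite senses, but the response was smaller in 80.5% of 1190 differing genes that rose in GF skin and in 71.6% of 997 that fell, and a gene length trend is argued against by a ratio of 0.83 with the trend removed, below 1 by a little over 2 times that SE. A lower effective dose of MC903 and an effect of the microbes or another difference between the housings, which was not tested, cannot be told apart, because of 9 lists called in both responses at the preset correlation 2 were reduced by the amount that ratio needs, within the SE of their median, 1 was reduced more and 3 less, and 3 (hair follicle, antimicrobial and IL-17 axis) had an SE above that amount and decide nothing. Those 2, stress keratinocyte (-1.13, SE 0.27, needed -1.12) and cornified envelope genes (-0.25, SE 0.2, needed -0.25), went with a lower dose, as did Cyp24a1 (-1.16, SE 0.45, adjusted p = 0.099, needed -1.1). Clock (0.61, SE 0.17, needed 0.24), proliferation (0.06, SE 0.06, needed -0.27), muscle (0.01, SE 0.05, needed 0.08) and Schwann cell genes (-0.04, SE 0.1, needed 0.13) went against one that reduced every list by the same share. The vitamin D list, called in neither response, had a median difference of -0.01 (camera adjusted p = 0.91). Of its 14 genes 2 were more positive and 1 more negative. Under MC903 4 of them, S100g included, were higher in GF skin and 2, Cyp24a1 included, lower. Part of the stress list's difference lay in ethanol skin, which received no MC903 (median 0.4 for GF minus SPF). The needed amounts leave out the SE of the ratio, which these lists help to set.

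Muscle, interferon and dendritic cell lists were called higher in GF than in SPF ethanol skin at the preset correlation, calls that ended with an estimated correlation (adjusted p = 0.12, 0.2 and 0.36). A gene length trend as the whole cause is argued against by medians of 0.61 (SE 0.1), 0.69 (SE 0.12) and 0.53 (SE 0.1) with the trend removed. A lower share of epidermis in the GF samples would raise the markers of every other tissue alike, but the medians were 0.7 (SE 0.1) for muscle, 0.41 (SE 0.17) for cartilage, 0.26 (SE 0.18) for adipocyte, 0.19 (SE 0.13) for endothelial, 0.13 (SE 0.12) for nerve and 0.04 (SE 0.12) for melanocyte genes, with only cartilage (0.38, SE 0.15, against 0.61 for muscle) within the summed SEs of muscle once the length trend was removed. For interferon genes with ethanol, whose median of 0.81 (SE 0.13) lay within the summed SEs of that of muscle, more muscle tissue in the GF samples and a difference by housing cannot be told apart, because 97.9% of the variance of the muscle mean lay between groups, but under MC903 more muscle as the whole cause is argued against by a median of 1.18 (SE 0.15) against 0.7 (SE 0.08) for muscle genes. More muscle in the pieces of ear taken may account for the muscle genes, and an effect of housing on all 3 lists was not tested.

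The genes with the most negative differences numbered 11 at a log2 limit of -3, namely the 8 most negative above with Fosl1 (-3.29), BC100530 (-3.1) and Ptgs2 (-3.03), which were chosen after their values were seen. Not all of these differences lay in MC903 skin alone. BC100530 was also higher in GF than in SPF ethanol skin. Sprr2a2 had means of 6.88 CPM in GF and 1.1 CPM in SPF ethanol skin, and of 210 and 721 CPM with MC903. Lower depth of the GF MC903 libraries is argued against by their lowest total of 41.8 M estimated counts, above the 36358294 of the lowest SPF MC903 library. That the quantification moved counts to other transcripts or overlapping genes and an effect of housing cannot be told apart for these genes, since only 1 of 11, Adnp, switched at least 16-fold between libraries of another group, against a mean of 0.041 in matched genes (permutation p = 0.04) and 1 of 9 at the other extreme. At 4-fold, a threshold set with these values in view, and at 8-fold, Camsap2 and Ablim1 also switched (3 of 11, permutation p = 1e-04 at both, the smallest that 10000 draws can give). In GF MC903 5 Adnp (0.201 CPM) and Dpm1-adnp (0.315 CPM), the second also chosen after its values were seen, were both near 0, against a plain move of counts from one to the other there.

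Other splits of the 6 libraries of a comparison number 10 with the real split and are too few for a share under 0.05, with 1 as large in each, the real one. The real and the highest other counts were 12149 and 1 for the SPF response, 11274 and 1 for the GF response, 3616 and 2 between ethanol groups, and 6871 and 3 between MC903 groups. For the difference of responses, 4 of 100 assignments of housing within treatment, drawn from 200, called as many genes as the real 2800, the real one included. Most other assignments mix the housings within a group, which raises the spread there, and the median of the others was 0 genes. They are therefore no fair measure of chance for the difference of responses, and chance is not excluded by them. The highest other called 7403 genes, points to a structure of the samples and is the swap of all housing labels within 1 treatment, which adds the housing differences of both treatments. The next called 3623.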

How the results depend on the processing

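Removal of the length trend and the exclusion of switching genes were chosen after the data were seen. Changes of direction between 2 values that both missed the threshold were not counted. Of 260 named gene results, 219 otherwise kept their direction and side of the threshold in every alternative run other than the muscle covariate, and 131 in that too. Of 44 called lists, 37 did so in every alternative other than the estimated correlation, with which 0 passed in each comparison (12, 11, 6, 10 and 5 with the preset in the order used below; 5, 5, 2, 5 and 3 at an unadjusted camera p under 0.05). With a 2-fold minimum, by its construction, the counts of genes fell to 5679 for the SPF response, 4175 for the GF response, 639 for their difference, 300 between ethanol groups and 1265 between MC903 groups. The muscle covariate gave 4018, 2252, 2590, 0 and 1 in that order in edgeR, with 681 and 2116 at an unadjusted p under 0.05 between housings. With 97.9% of its variance between groups, it raised the median standard error 3.4 to 3.8 times other than for the difference of responses. With the length trend removed 2300 genes differed between ethanol groups, and 11840 and 10640 changed in the SPF and GF responses. Of the main calls of these responses, 10067 of 12149 and 8627 of 11274 were called again in the same direction. Another 268 and 294 were called in the opposite direction. The similarity of the responses was 0.9 with the stricter filter, and the cause was not tested. Without 1 library at a time the counts were 11522 to 12204, 10375 to 11379, 2144 to 2786, 1511 to 4005 and 5672 to 6796 in that order, and the similarity 0.84 to 0.86. Of 3120 such values of named genes, 3024 kept their call, 86 lost it and 10 gained it, and of 528 for lists 26 lost it. Among named results past the threshold in either run, directions reversed for Ivl in GF skin on library totals (-0.14, adjusted p = 0.21, range 0.00065 to 0.21). They also reversed for Ccl17 in GF skin with the length trend removed (-0.88, adjusted p = 0.045, range 0.045 to 1), and the cause was not tested. Limma voom left 18 of 260 named results without their call and the covariate 105. Replicate labels do not show a pairing: a block on them gave 11950, 11073 and 2303 genes for the responses and their difference, ended 5 (Adnp, Ablim1, Mcm5, Mcm7 and Cxcl10) and began 1 (Cyp24a1) of 165 named calls, all for the difference of responses, ended 1 of 29 list calls (T cell, SPF) and began 1 (macrophage, GF), while deviations of libraries with the same label had correlations of -0.02 to 0.14 and only SPF2, SPF3 and GF1 had their own label as best partner. The block was not applicable between housings, nor the fit of only the libraries compared to the difference of responses, and a pseudocount played no part in tests on counts. Depth limits Il4, Il13, Il31, Reg3g and Il17a, which summed to 25 counts or fewer per group.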

Other observations

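The 5 gene groups and the chromosome test in this part were chosen after the data were seen, so their p-values, adjusted over the 5 groups with an estimated correlation, come from the data that led to the choice. Skint genes, a family whose member Skint1 selects epidermal gamma delta T cells, fell in 11 of 11 cases with MC903 in SPF skin (median -2.76, adjusted p = 0.058) and in 9 of 11 in GF skin (median -1.05, adjusted p = 0.16). The difference was more positive in GF skin in 8 of 11 cases, with a median of 1.72 (adjusted p = 0.015), including Skint4 (2.88), Skint5 (2.45) and Skint9 (1.72). Between MC903 groups 9 of 11 were higher in GF skin (median 1.98, adjusted p = 0.015), and between ethanol groups the median was -0.03 (adjusted p = 0.86). All 13 glycolysis genes rose in both housings (medians 1.87 and 1.16, adjusted p = 0.058 and 0.1). Their response was smaller in GF skin in 10 of 13 cases, with a median of -0.69 (adjusted p = 0.016), including Ldha (-0.71), Pgk1 (-0.8) and Gapdh (-0.99). In GF skin 9 of 13 were higher with ethanol (median 0.27, adjusted p = 0.2) and 9 lower under MC903 (median -0.32, adjusted p = 0.079), so the difference holds parts from both treatments. Hif1a, a transcription factor that drives glycolysis genes and was named here after its value was seen, had a difference of -1.53 (adjusted p = 0.00044).

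NRF2 target genes, of the oxidative stress response, had a more negative response in GF skin in 5 of 9 cases and a more positive one in 1, with a median of -0.61 (adjusted p = 0.015), including Gsta4 (-2.12), Srxn1 (-1.44) and Nqo1 (-1.05), a gene also held by the aryl hydrocarbon receptor list. Under MC903, 8 of 9 were lower in GF skin and 1 higher (median -0.82, adjusted p = 0.015), and with ethanol 2 were lower and 2 higher (median -0.13, adjusted p = 0.86). Genes of antigen processing for MHC class I were higher in GF skin in 9 of 10 cases with ethanol (median 0.62, adjusted p = 0.036) and in 10 of 10 with MC903 (median 1.12, adjusted p = 0.015), including Tap1 (0.55 and 1.27), B2m (0.55 and 1.17) and Psmb9 (1.01 and 1.38). Sterol synthesis genes had a more negative response in GF skin in 8 of 16 cases (median -0.28, adjusted p = 0.14) and were lower under MC903 in 10 of 16 (median -0.45, adjusted p = 0.12), against 4 lower and 2 higher with ethanol (median -0.08, adjusted p = 0.8).

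Some genes separated the housings or switched between libraries. Ugt1a6b lay between 69.4 and 87.1 CPM in GF libraries and between 6.36 and 11.8 in SPF libraries, and Ugt1a6a between 4.5 and 15.1 and between 26.3 and 37.1. Erdr1 lay between 104 and 211 CPM in SPF libraries and between 0 and 21.2 in GF libraries. Adnp was at 0.0771 CPM in SPF MC903 2, against 79.6 and 76.7 in the other 2 of that group, and Dpm1-adnp, also named after its values were seen, was at 112 CPM there and at 0 in the other 2.

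A hypothesis was that a chromosome segment differs between the GF and SPF mice. Of 117 genes that differed by at least 2-fold in the same direction in both housing comparisons, 55 were higher and 62 lower in GF skin. The fullest window of 30 Mb, on chromosome 13 from 12565818 to 40288011, held 10 of them, against a 95th percentile of 9 genes for the fullest window in random placements (permutation p = 0.043). But 4 of the 10 are histone genes under 1 name stem, and the 7 name stems in the window lay below the 95th percentile of 9 stems in such placements (permutation p = 0.63). Whether a segment differs thus stays open.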
